A study of Mus musculus with 7 samples.

How the data were processed

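The 7 libraries were ATAC-seq profiles of RAW264.7 cells made from 50000 cells each and read as paired ends of 100 bp, per the labels' protocols. Treated cells were taken after 4 h with RANKL (50 ng/ml), with RANKL and I-BET (500 nM) or with I-BET. Untreated, RANKL and RANKL+I-BET had 2 libraries each, and I-BET without RANKL had 1. A first replicate of I-BET was not given in the sources used here.

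Per the submitters' processing notes, the tools were FastQC, cutadapt, Bowtie2, Picard, bedtools, SAMtools and MACS2 on mm10, with no versions or settings stated. The authors deposited 1 peak list per library, so peaks were called per sample and not on pooled samples. Each deposited line gives start, end and summit position, a score, a fold (the ratio of pileup to local background), a -log10 p-value and a -log10 q-value. The deposited score equalled the whole part of 10 times the deposited -log10 p in 100% of lines. The lowest deposited -log10 p was 2.008, and peaks with a -log10 q under 1 made up 0.265% to 13.4% of a list. Score, fold and -log10 values are the authors' own and were used only to describe, rank or filter peaks within 1 list. Read counts per library are not given, so depth was described by the background pileup that the deposited folds imply and by the number of peaks, 975394 in all.

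Overlapping or book-ended peaks of all lists were joined into 344401 regions, and a library counted as calling a region when at least 1 bp of its peaks lay in it. A change within a region called in both groups was therefore not measured. For each of 3 comparisons (RANKL against untreated, RANKL+I-BET against RANKL, RANKL+I-BET against untreated), regions were sorted into those called in both libraries of 1 group and neither of the other, and mixed regions, called in 1 library of each group. The grouping ratio is the log2 of the geometric mean of the first and second class over the geometric mean of the 4 mixed patterns. It is 0 when libraries differ in sensitivity only, but it can leave 0 when they also differ in noise. Intervals came from 1000 bootstrap draws of the 21 chromosomes. They hold the libraries fixed, so they cover no variation between libraries. With 2 libraries against 2 there are 3 splits, so counts of regions were given without a p-value. A replicate block used only the mixed patterns with 1 call in each pair of equal number. The labels do not say that a number marks a day or batch, so the numbers were not taken as pairing the samples.

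Regions were assigned to the nearest of 21887 protein-coding genes of a RefSeq table for GRCm38.p6 within 100 kb, which covered 91.2% of regions. The plan named the nearest transcription start, but the table holds no strand, so distance was taken to the gene body, and the share within 1 kb of either gene end stands in place of promoters. The planned search for 18 transcription factor motifs, with its base composition strata and its smaller window, was not run, because no genome sequence was held. The 13 gene lists were osteoclast, AP-1 and early response, NF-kB, inflammatory cytokine, interferon response, macrophage identity, Myc and ribosome biogenesis, BET and elongation, oxidative phosphorylation, and markers of B lymphocytes, T lymphocytes, fibroblasts with osteoblasts, and granulocytes with erythroid cells. Of their 263 genes 261 were in the table. The lists, the tests and the alternatives were fixed before the data were examined, except those named below as chosen after the data had been seen.

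Lists were tested by two-sided Fisher's exact test, regions of 1 class against mixed regions, inside against outside the list, with Benjamini-Hochberg adjustment over 78 tests; 95% intervals of these odds ratios used the normal approximation, with 0.5 added to each cell where 1 was 0. Single genes with at least 5 such regions were tested in the same way within each comparison, and list members also adjusted over the list alone. Without untreated replicate 1, only regions of the first group were tested, adjusted over the 26 list tests, with the 4 location tests as another family, and again against crossed mixed regions alone. These tests count regions as units, which are not replicates. Genes were named by a rule: the 8 genes with the smallest p in each direction among those with at least 3 regions of the class, list members with at least 2 such regions (at most 4 per list and direction), and always Nfatc1, Fos, Myc, Irf8, Brd2, Acp5 and Ctsk. Some genes that the rule names are not reported here. Positions were the 3 of each class with the largest -log10 p in replicate 1. For regions called in a further library, log2 odds ratios were given with bootstrap intervals, and shares with exact Clopper-Pearson 95% intervals, which cover counting error only.

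The alternatives were a -log10 q of at least 5, lists of equal length (117175 peaks), peaks covering at least 50% of a region, genes within 50 kb, another comparator, 10000 random gene lists, the replicate block and leaving out each library. Chosen after the data had been seen were strong calls (the 60000 peaks of a library with the largest -log10 p), leaving out untreated replicate 1 in the list tests and further libraries, mixed and opposite classes as comparators, the location tests, and the 35 splits of the 7 libraries into 4 and 3. The log2 ratio of a split is the log2 geometric mean of the regions called in all libraries of 1 side only and of those in all of the other side only, less the median over the 35 splits.

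The procedures were tested on simulated data with 344401 regions for RANKL against untreated. In 1 draw with no effect planted, 0 of 26 list tests and 0 of 3447 genes were called. Its blocked grouping ratio was 0.05 (0.02 to 0.08), so this interval missed 0 with no effect. Over 20 other draws with no effect the blocked ratio lay between -0.03 and 0.03. With a difference between replicate numbers and no effect, the grouping ratio lay between -0.86 and -0.80 over 20 draws and the blocked ratio between -0.03 and 0.05. With all replicate 1 libraries made equally noisy and no effect, they lay between -0.14 and -0.09 and between -0.02 and 0.03. No simulation made untreated replicate 1 alone noisier. A planted list was called, the only 1 of 26 tests, and 9 of 10 planted genes were called. These planted effects were large (adjusted p = 5.9e-15 for the list, Fisher's exact test). Detection of weaker effects on lists or genes was not tested. Of 3000 planted regions 35.9% were recovered. With a difference between replicate numbers as well, 29.7% were recovered and the blocked ratio was 0.06 (0.01 to 0.10). This was hardly above the 0.05 reached with no effect, so the blocked ratio did not clearly detect these regions. Lists and genes were planted only without such a difference. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used.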

Results

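Open chromatin was mapped by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in RAW264.7 cells, a mouse monocyte-macrophage line that can be driven toward osteoclasts, the cells that resorb bone. The inducer was RANKL, the cytokine that starts osteoclast development, at 50 ng/ml, and the inhibitor was I-BET at 500 nM, which blocks the acetyl-lysine pockets of BET proteins such as Brd2. The 7 libraries formed 4 groups: untreated cells (2 libraries), RANKL (2), RANKL with I-BET (2) and I-BET without RANKL (1, labelled replicate 2), the treated cells being taken after 4 h. The labels do not say whether replicates were separate cultures, so they may be technical.

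The peak lists held 117175 to 166369 peaks per library, and joining all lists gave 344401 regions on mm10, with a median length of 308 bp. Of these regions 43170 were called in all 7 libraries, and 22.4% of those lay within 1 kb of an end of a protein-coding gene, against 4.63% after the gene ends had been moved by 1 Mb. Read depth is not given in the files. The background pileup that the authors' folds imply, a proxy for depth, ran from 1.12 in I-BET replicate 2 to 13.8 in RANKL+I-BET replicate 2. In untreated replicate 1, 42.9% of the regions were called in no other library, against 8.95% in untreated replicate 2 and 10.8% to 27.1% in the other 5. Of the peaks of untreated replicate 1, 25.3% had a deposited -log10 q of at least 5, against 61.3% in untreated replicate 2. The tests on strong calls, on gene ends and on regions without untreated replicate 1, and those against mixed regions in the libraries with I-BET, were chosen after the data had been seen.

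The first comparison asks which regions open in the first hours of RANKL. Peaks present in both RANKL libraries and in neither untreated library (RANKL-only regions) were found at some regulators of osteoclast development and not at others, and osteoclast genes as a list had no more of them than of mixed regions (log2 odds ratio 0.01, p = 1.0, Fisher's exact test). Nfatc1, the transcription factor that drives osteoclast differentiation, had 3 on chromosome 18, at 80563513 to 80564125, 80583323 to 80584103 and 80723042 to 80723732, all outside the gene (80606205 to 80713071). Nfkbiz, an inducible nuclear cofactor of NF-kB, had 4, and Jun, an AP-1 subunit induced early by RANKL, had 4 with 1 region of the opposite kind. Atp6v1c1, a subunit of the proton pump that acidifies the resorption pit, had 4. Fos and Myc, early transcription factors downstream of RANKL, and the osteoclast enzyme genes Acp5 and Ctsk had 0. Much of the Nfatc1 gene lay in long regions called in all 7 libraries, such as 80695695 to 80710878. A peak gained within a shared region could not count as RANKL-only, at Nfatc1 or at the genes with 0.

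Over the genome 8594 regions were RANKL-only and 1910 were untreated-only, present in both untreated libraries and in neither RANKL library. Another 21639 were mixed, with 1 call in each group, and 46407 were called in all 4 libraries. RANKL-only regions were 4.50 times as many as untreated-only regions. Differences between libraries also move this ratio: 1 draw of simulated libraries with no effect of the group gave 12334 and 6603 regions. The grouping ratio, the log2 of the geometric mean of both classes over that of the mixed patterns, was -0.26 (95% interval -0.32 to -0.19, 2 libraries against 2), because most mixed regions (15139) were shared by libraries of the same replicate number. With the 6500 mixed regions that cross the numbers as the only comparator, as in a replicate block, the ratio was 0.35 (0.32 to 0.38). These bootstrap intervals hold the libraries fixed, so they cover no variation between libraries. Simulations with no effect and all replicate 1 libraries made equally noisy also gave grouping ratios below 0, from -0.14 to -0.09. Their blocked ratios ran from -0.02 to 0.03. No simulation made untreated replicate 1 alone noisier, although 42.9% of its regions were its own, against 24.8% in RANKL replicate 1. Within replicate number 1, 82076 regions were called in RANKL alone and 67401 in untreated alone, and within number 2, 38316 and 22976. With 2 libraries against 2 only 3 splits exist, so no p-value was computed for these counts. Requiring fewer libraries raised them: RANKL-only regions numbered 33470 without RANKL replicate 1, 55157 without RANKL replicate 2 and 31604 without untreated replicate 2, and untreated-only regions numbered 3223, 3956 and 62764 in that order, and 17754 without untreated replicate 1.

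**Figure D1:**
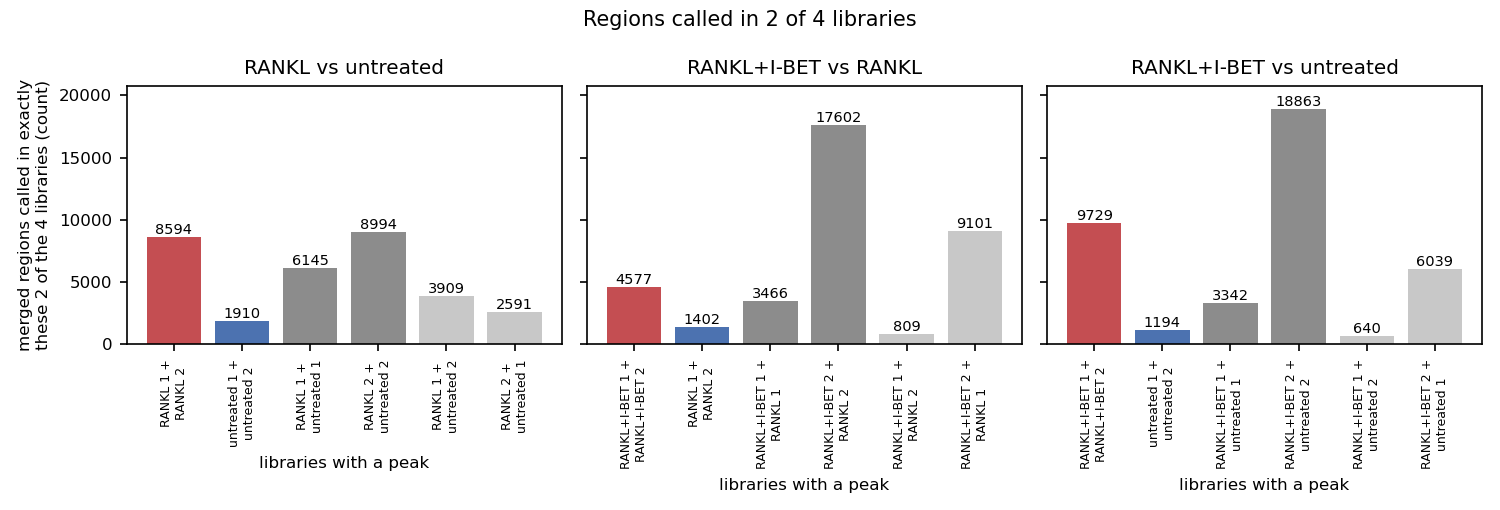
Number of merged regions called in exactly 2 of the 4 libraries of each comparison (vertical axis, count), by the pair of libraries that has a peak (horizontal axis); red and blue bars are pairs from 1 group, dark grey bars pairs with the same replicate number and light grey bars pairs that cross group and number. In RANKL against untreated, 8594 regions were shared by both RANKL libraries, more than the 3909 and 2591 of the crossed pairs, and 8994 were shared by the libraries numbered 2.

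The strongest peaks had a larger excess of RANKL-only over untreated-only regions, a ratio that differences between the libraries also move. Regions whose peaks ranked among the 60000 with the largest -log10 p in both RANKL libraries, with no peak in untreated cells, numbered 344, against 13 of the reverse kind. The crossed mixed patterns held 61 and 19 such regions, and the patterns of libraries with the same number 171 and 633. The 344 thus exceeded both crossed counts but not the 633 of the libraries numbered 2, so the reading depends on the comparator. Among the 344 were a region 1970 bp from Rel, an NF-kB subunit, at 23772640 to 23773238 on chromosome 11, and 1 at 88490782 to 88491309 on chromosome 4, 30979 bp from Ifnb1, which encodes interferon beta (both chosen after their values were seen). All of the 344 were also called in RANKL+I-BET replicate 2, and 77.9% in RANKL+I-BET replicate 1, but the other patterns of strong calls had shares of 60.2% to 100% and 41.9% to 90.6% in these libraries.

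RANKL-only regions lay at the ends of genes less often than mixed regions did. Of the 8594 regions 4.41% (Clopper-Pearson 95% interval 3.99% to 4.87%, counting error only) were within 1 kb of a gene end, against 7.01% of mixed regions (6.67% to 7.35%) and 9.32% of untreated-only regions (8.05% to 10.7%). With the gene ends moved by 1 Mb, 4.23% of all regions were near one. The log2 odds ratio against mixed regions was -0.71 (adjusted p = 1.17e-16 over 24 tests of location, two-sided Fisher's exact test), and -0.73 against the crossed mixed regions. They also lay less often inside genes, 53.7% against 58.0% of mixed and 64.1% of untreated-only regions. Without untreated replicate 1 the log2 odds ratio at gene ends was -0.71 as well, and -0.59 against crossed mixed regions. These tests treat regions, not libraries, as the unit.

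By list, osteoclast genes had 22 RANKL-only regions at 12 of 25 members, beside 55 mixed regions (log2 odds ratio 0.01, 95% interval -0.70 to 0.73). These included Itgb3, an integrin chain of the osteoclast attachment zone, and Jdp2, an AP-1 family member needed for osteoclast formation, with 2 each. NF-kB pathway genes had 19 at 12 of 25 members beside 31 mixed (0.63, -0.20 to 1.45), among them Nfkb1, which encodes a DNA-binding subunit, with 3, and the adaptor genes Traf1 and Traf2 with 2 each. AP-1 and early response genes had 11 at 5 of 25 members beside 49 mixed (-0.82, -1.77 to 0.12), with 2 each at Dusp5, Spred1 and Spry2, which restrain ERK signalling. Inflammatory cytokine genes had 11 beside 27 mixed (0.04, -0.98 to 1.05), with 2 each at the chemokine gene Cxcl1, the cyclooxygenase gene Ptgs2 and Il1rn, which encodes the interleukin-1 receptor antagonist. Interferon response genes had 10 beside 28 (-0.15, -1.20 to 0.89), with 2 each at Gbp3, Ifi44 and Oas3.

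Macrophage identity genes had 23 RANKL-only regions at 13 of 27 members beside 55 mixed (0.07, -0.63 to 0.78). Runx1 and Zeb2, transcription factors of the myeloid lineage, had 4 each, the pattern receptor gene Tlr2 had 3 and Cebpb, a myeloid transcription factor, had 2, while Runx1, Zeb2 and Cebpb also had 1 untreated-only region each. Genes of Myc and ribosome biogenesis had 11 beside 45 (-0.70, -1.65 to 0.25), with 3 each at Eif4e, which encodes the cap-binding translation factor, and Nolc1, a nucleolar protein gene. Genes of BET proteins and transcription elongation had 3 beside 24 (-1.67, -3.40 to 0.06), of which 2 lay at the elongation factor gene Ell2, and oxidative phosphorylation genes had 3 beside 21 (-1.48, -3.22 to 0.27). Markers of other cell types had 5 regions for B lymphocytes, 2 for T lymphocytes, 6 for fibroblasts and osteoblasts and 2 for granulocytes and erythroid cells, beside 9, 14, 19 and 2 mixed regions. Of the 26 tests of this comparison 0 passed by two-sided Fisher's exact test, and 0 had an unadjusted p under 0.05 (lowest adjusted p = 0.692). When untreated replicate 1 was left out, which leaves 1 untreated library, 3 lists had a smaller share of RANKL-only than of mixed regions: AP-1 and early response (log2 odds ratio -1.36), BET and elongation (-2.29) and Myc and ribosome biogenesis (-1.26), each with an adjusted p = 0.0395 by Fisher's exact test over 26 list tests. Against the 5222 of those 16262 mixed regions that cross the replicate numbers, a smaller comparator, 0 lists passed, though the log2 odds ratios were of similar size at -1.17, -2.06 and -1.38 in that order (adjusted p = 0.577, 0.577 and 0.35, Fisher's exact test).

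**Figure D2:**
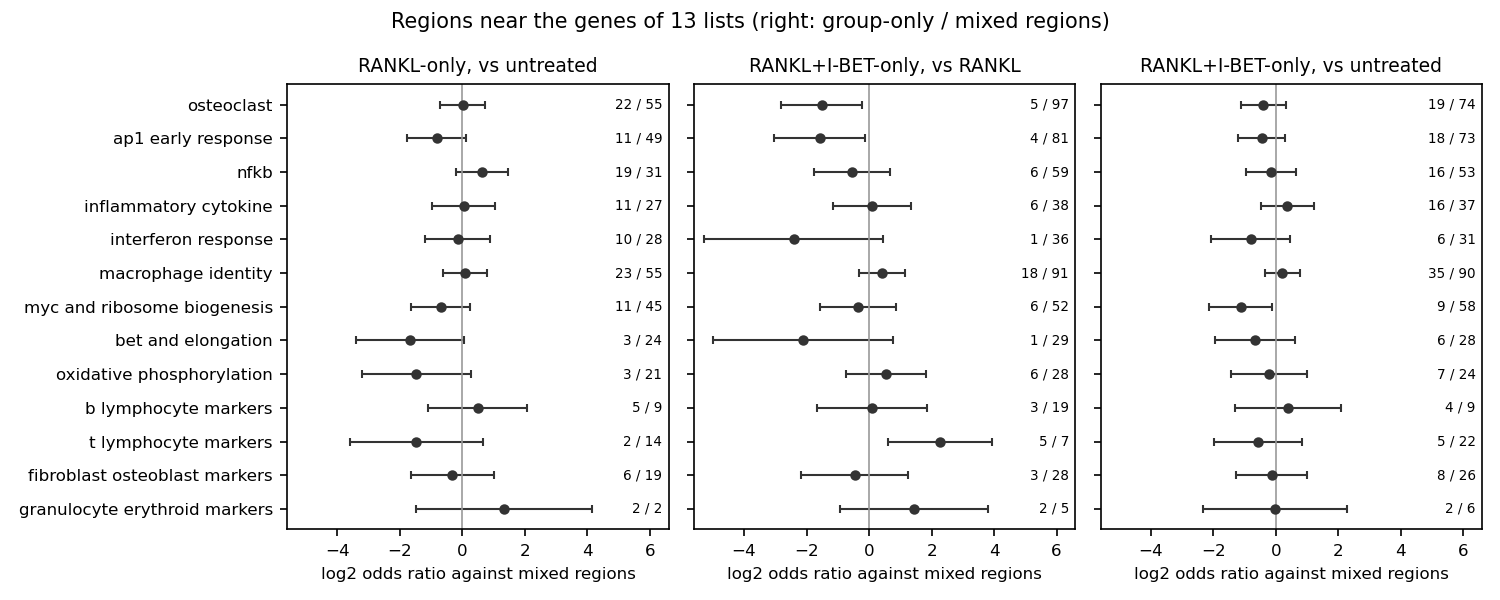
Log2 odds ratio (points, with 95% intervals as bars) of regions near the genes of each list, for regions called in both libraries of the first group and neither of the second, against mixed regions; the counts at the right are group-only and mixed regions. Near osteoclast genes the RANKL-only ratio was 0.01, and all 13 intervals of that comparison span 0.

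Gene by gene, no locus passed. Of 1575 genes with at least 5 regions of the 3 kinds 0 passed Fisher's exact test after adjustment, 114 had an unadjusted p under 0.05, and 0 of 32 list members passed when adjusted over the list alone. The smallest p for RANKL-only regions was at Magi1, a scaffold protein of cell junctions, with 10 RANKL-only and 3 mixed regions (log2 odds ratio 3.07, adjusted p = 0.277, Fisher's exact test). Pde1c had 6, Utrn 8, Ppm1h 9, and Etl4, Nrxn3, Scg5 and Slc17a6 had 5 each. For untreated-only regions the smallest p were at Adap1, Ppp6r2, Dnmt3a, Hr, Ccdc167 and Notch1 with 3 each and at Rere and Tns1 with 4 each, beside which Dnmt3a had 3, Rere 4 and Adap1 and Tns1 1 RANKL-only regions (all adjusted p = 1.0, Fisher's exact test). Irf8, a transcription factor that restrains osteoclast formation, had 3 untreated-only and 1 RANKL-only region beside 8 mixed. The gelatinase gene Mmp9, Itgav, Fosl2, Oasl1 and Nrf1 had 2 untreated-only regions each, and Brd2 had 0.

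The RANKL-only positions with the largest deposited -log10 p in RANKL replicate 1 were 175851282 to 175852106 on chromosome 1 (47.97, 29074 bp from Exo1), 119922749 to 119923588 on chromosome 4 (46.8, inside Hivep3) and 117025645 to 117026285 on chromosome 7 (46.8, no protein-coding gene within 100 kb). The untreated-only ones were 53818676 to 53819443 on chromosome 11 (19.19 in untreated replicate 1, 40686 bp from the interferon regulatory factor gene Irf1), 51927068 to 51927543 on chromosome 11 (16.11, nearest to Cdkn2aipnl) and 25430401 to 25430944 on chromosome 7 (15.11, nearest to the chemokine gene Cxcl17). All 3 RANKL-only positions were also called in both RANKL+I-BET libraries, as was the untreated-only position near Irf1, and the other untreated-only positions were called in 1 of them each. Scores, folds and -log10 values of peaks are the authors' and rank peaks within 1 list only.

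**Figure D3:**
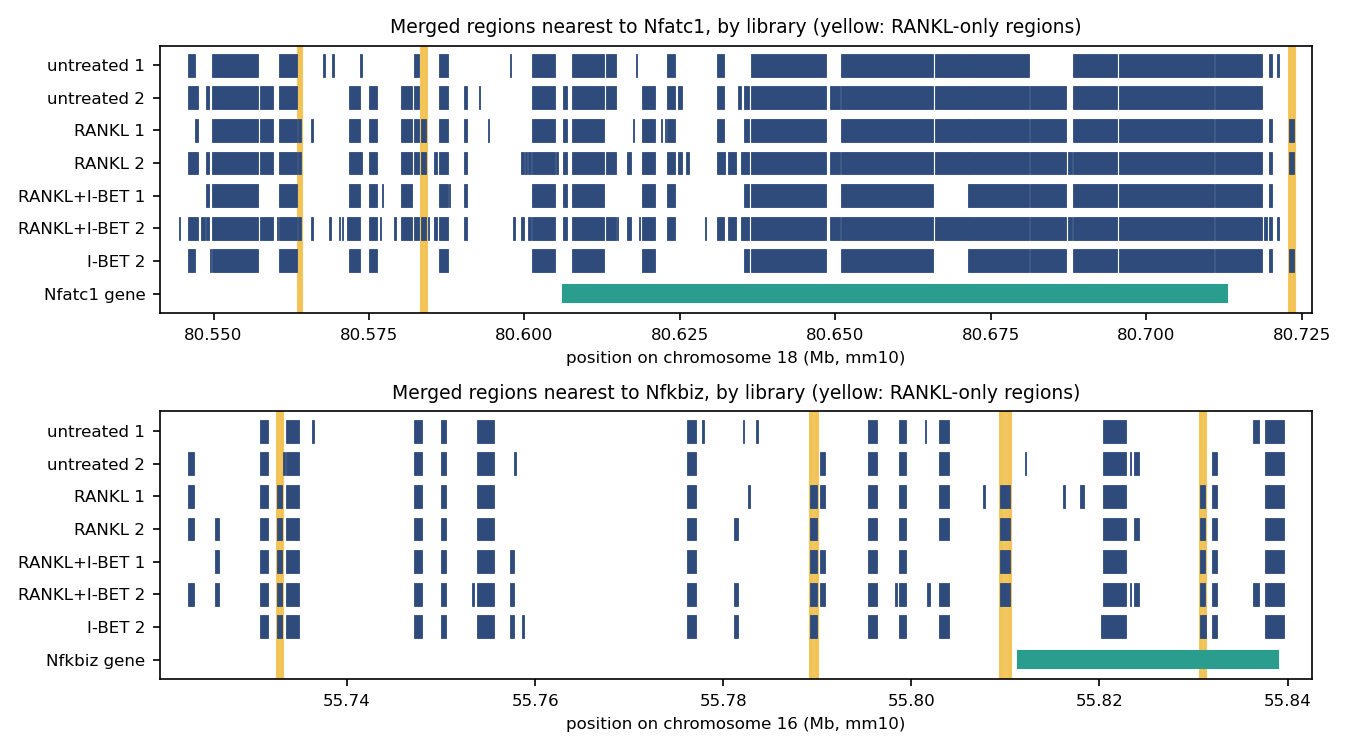
Merged regions assigned to Nfatc1 (chromosome 18) and Nfkbiz (chromosome 16), with position in Mb on the horizontal axis and 1 line per library; a bar spans the whole merged region wherever the library has a peak in it, green marks the gene and yellow the RANKL-only regions. The 4 RANKL-only regions at Nfkbiz were called in both RANKL+I-BET libraries, while 2 of the 3 at Nfatc1 were called in RANKL+I-BET replicate 2 alone of the pair and 1 in neither.

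The next question was what became of RANKL-only regions when I-BET was added with RANKL. All 4 regions at Nfkbiz and all 4 at Jun were called in both RANKL+I-BET libraries, as were 2 of 4 at Atp6v1c1 and both at Jdp2. None of the 3 at Nfatc1 was called in both, though 2 were called in RANKL+I-BET replicate 2. Over all RANKL-only regions the share called in both was 37.4%, so single genes with few regions say little. The Nfatc1 region at 80723042 to 80723732 was absent from both, as were the RANKL-only regions of Oscar, a costimulatory receptor gene of osteoclasts (2), and 1 at Nfkb1. Further list members with 1 absent region each were Src, a kinase gene needed for bone resorption, Bcl3, an atypical NF-kB inhibitor gene, Runx1, Ifi44, Bcl11b and Camp, while Nolc1 had 2 (all chosen after their values were seen). The absent Nfatc1 region and the Oscar region at 3615956 to 3616400 were called in the I-BET library without RANKL.

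Of the 8594 RANKL-only regions 3213 (37.4%, 36.4% to 38.4%) were called in both RANKL+I-BET libraries, against 14.4% of untreated-only (12.9% to 16.1%) and 22.2% of mixed regions (21.6% to 22.7%). The log2 odds ratio was 1.83 against untreated-only regions (95% interval 1.69 to 1.98) and 1.07 against mixed regions (0.98 to 1.15). In RANKL+I-BET replicate 1 alone it was 1.34 (1.17 to 1.53), with 39.9% of RANKL-only regions called, and in replicate 2 alone 2.68 (2.52 to 2.83), with 85.2%. In neither library were 12.3% of RANKL-only regions (1056), against 46.2% of untreated-only and 26.3% of mixed regions. Leaving out untreated replicate 1 lowered the ratio against mixed regions to 0.66 (0.57 to 0.74), and to 0.15 (0.05 to 0.25) against mixed regions that cross the replicate numbers. In RANKL+I-BET replicate 2 alone, the ratio against all mixed regions without untreated replicate 1 was below 0, at -0.27 (-0.40 to -0.16). That against crossed mixed regions was above 0, at 0.67 (0.55 to 0.80). For RANKL+I-BET replicate 1 alone these ratios were 0.70 (0.62 to 0.78) and 0.096 (0.017 to 0.17).

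In the single I-BET library without RANKL, 32.1% of RANKL-only regions were called (31.1% to 33.1%), against 20.1% of untreated-only (18.3% to 22.0%) and 32.1% of mixed regions (31.5% to 32.7%). The log2 odds ratio was 0.91 against untreated-only regions (0.73 to 1.07), -0.0019 against mixed regions (-0.13 to 0.13) and 0.25 against crossed mixed regions (0.13 to 0.36). It was -0.04 with peaks at a -log10 q of at least 5 (-0.89 to 1.22), and -0.66 against mixed regions without untreated replicate 1 (-0.76 to -0.58), so the direction depended on the comparator. Between RANKL+I-BET replicate 2 and I-BET replicate 2, which share a replicate number, the log2 odds ratios against untreated-only regions differed by 1.77 (1.53 to 2.01), and those against crossed mixed regions by 1.13 (1.03 to 1.25). With a -log10 q of at least 5 these differences were 3.57 (1.67 to 5.04) and 2.36 (1.68 to 3.12), with lists of equal length 2.53 and 1.44, and with 50% of the region covered 2.45 and 1.61. The background pileup of these libraries was 13.8 and 1.12, and no second I-BET library was held, so these are values without a replicate.

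**Figure D4:**
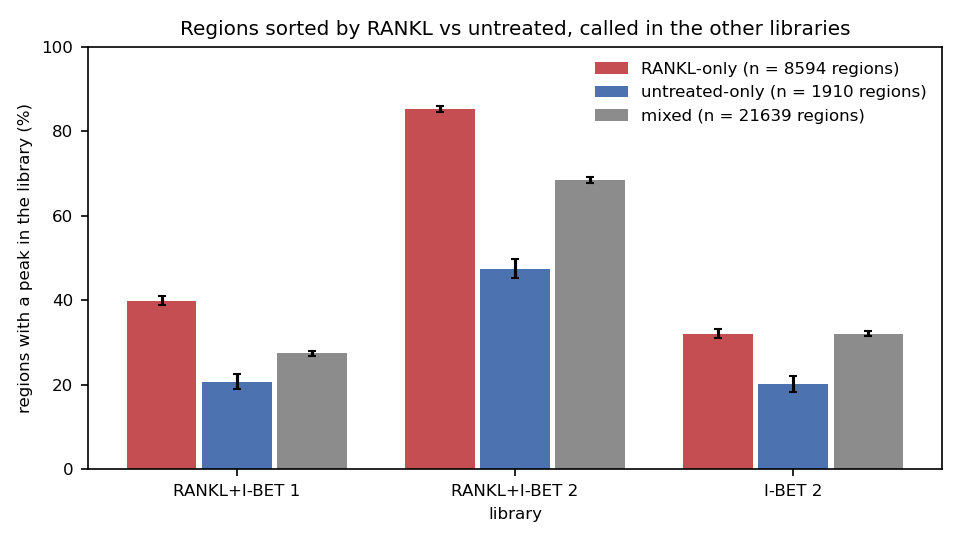
Percent of RANKL-only (n = 8594), untreated-only (n = 1910) and mixed (n = 21639) regions with a peak in each library with I-BET (vertical axis, percent; error bars, Clopper-Pearson 95% intervals for counting error). RANKL-only regions were called in 39.9% and 85.2% of cases in the RANKL+I-BET libraries and in 32.1% in the I-BET library, where mixed regions also stood at 32.1%.

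The second comparison asks which regions differ between RANKL with I-BET and RANKL alone. Regions in both RANKL+I-BET libraries and in neither RANKL library (inhibitor-only) lay most often, among list members, at Runx1, with 7 and 1 of the reverse kind beside 14 mixed. Marco, a scavenger receptor gene of macrophages, Fos, Irf8, Cebpb and the NF-kB subunit gene Rela had 2 each, and Odc1, which encodes the first enzyme of polyamine synthesis, had 3. The reverse kind, in both RANKL libraries and in neither RANKL+I-BET library (inhibitor-absent), included 2 at Oscar (3610659 to 3610869 and 3615956 to 3616400 on chromosome 7), 2 at Nolc1 and 1 at Nfatc1. Myc, Brd2 and Acp5 had 0 of either kind and Ctsk 1 inhibitor-only region.

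In all, 4577 regions were inhibitor-only, 1402 inhibitor-absent and 30978 mixed, and 65831 were in all 4 libraries. The ratio of inhibitor-only to inhibitor-absent regions was 3.26, which differences between the libraries also move. The grouping ratio was -0.86 (-0.91 to -0.79), and -0.10 (-0.17 to -0.03) against the 9910 crossed mixed regions, though with a -log10 q of at least 5 the latter was 0.054 (-0.53 to 0.84). Within replicate number 1, 33224 regions were called with the inhibitor alone and 63128 without it alone, and within number 2, 60307 and 17900, which point in opposite directions. Inhibitor-only regions numbered 45773 and 27670 without RANKL+I-BET replicate 1 and 2, and 10010 and 9322 without RANKL replicate 1 and 2. Inhibitor-absent regions numbered 14097 without RANKL+I-BET replicate 2, and 16753 and 41332 without RANKL replicate 1 and 2. Among the strongest peaks only 3 regions were inhibitor-only and 0 inhibitor-absent, against 23 and 0 in the crossed patterns and 108 and 643 in those of equal number; the 3 lay near Calm3, Nhsl1 and Prdm1, which encodes a repressor that osteoclasts use to silence macrophage genes (chosen after their values were seen).

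No gene list passed in this comparison. Of 26 tests 0 passed by Fisher's exact test, 3 had an unadjusted p under 0.05, and the lowest adjusted p was 0.472. These 3 were osteoclast genes, with 5 inhibitor-only beside 97 mixed regions (log2 odds ratio -1.52), AP-1 and early response genes, with 4 beside 81 (-1.58), and T lymphocyte markers, with 5 beside 7 (2.27). Macrophage identity genes had 18 beside 91 (0.42), NF-kB genes 6 beside 59 (-0.54), inflammatory cytokine genes 6 beside 38 (0.10), interferon response genes 1 beside 36 (-2.41), Myc and ribosome biogenesis genes 6 beside 52 (-0.36), BET and elongation genes 1 beside 29 (-2.10) and oxidative phosphorylation genes 6 beside 28 (0.54), with 2 each at Cox4i1 and Ndufa9. B lymphocyte markers had 3, those of fibroblasts and osteoblasts 3 and those of granulocytes and erythroid cells 2.

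Of 1977 genes 0 passed Fisher's exact test after adjustment, 114 had an unadjusted p under 0.05, and 0 of 40 list members passed when adjusted over the list alone. The smallest p for inhibitor-only regions were at Gipc2 (4 regions), Fbxw7, which encodes a ubiquitin ligase component that targets Myc (7), Ranbp3 (4), Chchd6 (5), Inpp5a, Lama5 and Zan (4 each), all with adjusted p = 1.0 by Fisher's exact test. For inhibitor-absent regions they were at Megf6 (4), the DNA demethylation gene Tet3 (3), Syt14 (5), Lama5 and Atp8b2 (3 each), Plxna2 (5) and Ptprn2 (4), of which Plxna2 had 7 inhibitor-only regions, Lama5 4, Ptprn2 3, Syt14 2 and Tet3 1, the lowest adjusted p being 0.532 by Fisher's exact test. No location test passed after adjustment. Near gene ends were 6.18% of inhibitor-only, 7.63% of inhibitor-absent and 6.25% of mixed regions (adjusted p = 0.912 for inhibitor-only against mixed, Fisher's exact test). For inhibitor-absent against mixed regions the log2 odds ratio was 0.31 (adjusted p = 0.0607, Fisher's exact test). For inhibitor-only against inhibitor-absent regions it was -0.33 (adjusted p = 0.0847, Fisher's exact test).

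The inhibitor-only positions with the largest -log10 p in RANKL+I-BET replicate 1 were 3878503 to 3879500 on chromosome 11 (38.74, nearest to 4921536K21Rik), 34927579 to 34928117 on chromosome 5 (24.84, 859 bp from Msantd1) and 123146127 to 123146771 on chromosome 10 (19.02, inside Usp15). The first and second were also called in both untreated libraries. The inhibitor-absent positions were 143912275 to 143912499 on chromosome 2 (13.99, inside Bfsp1), 91401470 to 91402033 on chromosome 15 (13.16, inside Slc2a13) and 166791724 to 166792276 on chromosome 2 (12.34, nearest to Trp53rkb), the last of which, like that inside Slc2a13, was also called in untreated replicate 2.

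The third comparison sets RANKL with I-BET against untreated cells. Regions in both RANKL+I-BET libraries and in neither untreated library (combination-only) were found at some osteoclast genes, although the list as a whole had no excess of them (log2 odds ratio -0.39, p = 0.339, Fisher's exact test). Atp6v0d2, a proton pump subunit gene required for fusion of osteoclast precursors, had 5 and Atp6v1c1 4. Nfkbiz had 6, Runx1 7 with 1 of the reverse kind, Marco 4, Jun 4 with 1 of the reverse kind, and the chemokine gene Cxcl3 3 of its 5 regions. Fos and Irf8 had 2 each and Acp5 1, while Nfatc1, Myc and Ctsk had 0 of either kind and Brd2 had 1 of the reverse kind. Combination-only regions were also found at Lck, a T lymphocyte kinase gene (2), and at Ppargc1a, a regulator of mitochondrial genes (2).

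There were 9729 combination-only regions, 1194 of the reverse kind and 28884 mixed regions. The first were 8.15 times as many as the second, a ratio that differences between the libraries also move. The grouping ratio was -0.21 (-0.27 to -0.14), and with the replicate number as a block, against 6679 crossed mixed regions, it was 0.79 (0.72 to 0.87). Within replicate number 1, 54820 regions were called in RANKL+I-BET alone and 70049 in untreated alone, and within number 2, 71108 and 13361, so the numbers point in opposite directions. Combination-only regions numbered 61708 and 33245 without RANKL+I-BET replicate 1 and 2, and 30664 without untreated replicate 2, while the reverse kind numbered 4907 without RANKL+I-BET replicate 2, and 12513 and 60297 without untreated replicate 1 and 2. Among the strongest peaks 282 regions were combination-only and 1, inside Swap70, was the reverse, against 0 and 16 in the crossed patterns and 135 and 1738 in those of equal number. Of the 282, 98.2% were called in RANKL replicate 1 and 94.7% in RANKL replicate 2, where the other patterns had 68.9% to 100% and 7.41% to 100%. They included regions 89699 bp from Ptgs2 and 57174 bp from Bcl6, a transcriptional repressor gene (these genes and Swap70 were chosen after their values were seen).

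Combination-only regions also lay near gene ends less often, at 4.70% (4.29% to 5.14%), against 4.23% of all regions with the ends moved by 1 Mb, 6.57% of mixed regions and 10.4% of the reverse kind (log2 odds ratio -0.51 against mixed, adjusted p = 1.53e-11, Fisher's exact test). Of 26 list tests 0 passed by Fisher's exact test and 1 had an unadjusted p under 0.05, that of Myc and ribosome biogenesis genes with 9 combination-only beside 58 mixed regions (log2 odds ratio -1.12, adjusted p = 0.472). Without untreated replicate 1 this list passed, with a log2 odds ratio of -1.29 (adjusted p = 0.0395 over 26 list tests, Fisher's exact test), but not against the 848 crossed mixed regions then left (-0.49, adjusted p = 0.98). Macrophage identity genes had 35 beside 90 (0.21) at 19 of 27 members, osteoclast genes 19 beside 74 (-0.39), AP-1 and early response genes 18 beside 73 (-0.45), NF-kB genes 16 beside 53 (-0.16), inflammatory cytokine genes 16 beside 37 (0.36) and interferon response genes 6 beside 31 (-0.80). BET and elongation genes had 6 beside 28 (-0.65) and oxidative phosphorylation genes 7 beside 24 (-0.21). Markers of B lymphocytes, T lymphocytes, fibroblasts with osteoblasts, and granulocytes with erythroid cells had 4, 5, 8 and 2.

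Of 2286 genes 0 passed Fisher's exact test after adjustment, 140 had an unadjusted p under 0.05, and 0 of 46 list members passed when adjusted over the list alone. The smallest p was at Pdlim5, which encodes a scaffold of the actin cytoskeleton, with 9 combination-only and 1 mixed region (log2 odds ratio 4.74, adjusted p = 0.0722, Fisher's exact test). Then came Shroom3 with 6, the semaphorin receptor gene Plxna2 with 20 (beside 18 mixed), Cep128, Cpped1, Lhpp and Robo2 with 5 each and Golim4 with 8. With genes within 50 kb only, Pdlim5 and Plxna2 passed (adjusted p = 0.0333 each, Fisher's exact test). With the replicate block, Dnah8 and Lingo1 passed with fewer combination-only regions than other genes (3 and 1 beside 16 and 12 mixed, adjusted p = 0.0483 each, Fisher's exact test). For the reverse kind Nol4l and Plxna2 had 3 regions each (adjusted p = 1.0, Fisher's exact test).

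The combination-only positions with the largest -log10 p in RANKL+I-BET replicate 1 were 104383131 to 104383847 on chromosome 11 (37.61, inside Kansl1), 75781749 to 75782398 on chromosome 2 (36.5, 50103 bp from Agps) and 73271434 to 73272401 on chromosome 17 (34.29, nearest to Lclat1). All 3 were also called in RANKL replicate 1, as was 1 position of the reverse kind, near Sgms2. The positions of the reverse kind were 25769285 to 25769721 on chromosome 10 (11.32, no gene within 100 kb), 131495694 to 131496032 on chromosome 3 (10.42, 4420 bp from Sgms2) and 90309166 to 90309772 on chromosome 6 (10.42, inside Chst13).

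I-BET without RANKL, held as 1 library, allowed values only. Of the 51676 regions called in both untreated libraries 5306 (10.3%) had no peak in the I-BET library, against 2.71% to 9.50% in each of the 4 libraries with RANKL. Of such regions 5 of 17 at Nfatc1 were absent with I-BET, 5 of 19 at Irf8, 1 of 8 at Myc and 0 of 15 at Fos. At Brd2 1 of 3, at Acp5 1 of 4 and at Ctsk 0 of 4 were absent. The I-BET library had the lowest background pileup (1.12), and the 2.71% belonged to RANKL+I-BET replicate 2, with the highest (13.8). Depth could thus not be told apart from an effect of I-BET on absent calls. Regions in the I-BET library and in neither untreated library numbered 47611, or 38.5% of that library's regions, within the 28.2% to 39.9% of the libraries with RANKL. They numbered 15 at Irf8, 5 at Myc and 2 at Nfatc1, and by list 96 near macrophage identity genes, 66 near osteoclast genes and 34 near B lymphocyte markers, or 24.7%, 24.2% and 61.8% of the I-BET library's regions near each list. Without untreated replicate 2 the regions absent with I-BET numbered 72487 and those in I-BET alone 72747, and without untreated replicate 1 the former numbered 31927.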

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

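Of 120 alternatives run over 19 results, 67 kept the direction and the side of the threshold, or for counts stayed within 1.5 times, though several ratios among them moved far, as given below. The 67 include list and gene tests whose 0 calls stayed at 0, which says little about stability. Of the rest 46 counts moved further, 6 ratios reversed and 1 weakened. Chosen after seeing the data were strong calls, the list tests and further-library ratios without untreated replicate 1, and the comparators of mixed or opposite class. The motif search, its narrower window and its base composition strata were not run for lack of a genome sequence. No list was called under any alternative fixed before the data were examined, and read depth, which the files do not give, limits how far an absent call can be read as closed chromatin. Unless stated, the cause of a change was not tested.

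With a -log10 q of at least 5, which leaves fewer peaks, the counts of regions in the first group only and in the second only were 3797 and 109 for RANKL against untreated, 1815 and 16 for RANKL+I-BET against RANKL, 5012 and 6 for RANKL+I-BET against untreated, and 2224 and 1531 for I-BET against untreated; the log2 odds ratio of RANKL-only regions in the I-BET library became -0.040. With lists of equal length, which also hold fewer peaks, the grouping ratio of RANKL against untreated was -0.093 with an interval that reached 0 (-0.17 to 0.0025), and the first-group counts were 2498 for RANKL+I-BET against RANKL, 6135 for RANKL+I-BET against untreated and 30376 for I-BET. Requiring 50% of the region to be covered gave 1140 untreated-only regions against RANKL and 717 against RANKL+I-BET. With strong calls, which are fewer by construction, the counts were 344 and 13, 3 and 0, and 282 and 1 in the 3 comparisons. With genes within 50 kb, 2 genes passed for RANKL+I-BET against untreated.

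The replicate block turned the grouping ratio from -0.26 to 0.35 for RANKL against untreated and from -0.21 to 0.79 for RANKL+I-BET against untreated; by construction it drops the mixed regions shared by libraries of equal number. It moved RANKL+I-BET against RANKL from -0.86 to -0.10, and to 0.054 (-0.53 to 0.84) with a -log10 q of at least 5, called 2 genes for RANKL+I-BET against untreated and changed no list call. In the 4 libraries of each comparison, regions shared by equal numbers exceeded crossed ones by 1.22, 1.53 and 2.01 (log2), a hint from the data and not from the design. Under the block with untreated replicate 1 left out, the log2 odds ratio in the I-BET library was -0.18; it was -0.00194 against mixed regions and -0.66 without untreated replicate 1.

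Leaving out 1 library, which by construction asks fewer libraries to share a call, gave 10849 to 55157 RANKL-only and 3223 to 62764 untreated-only regions, 9322 to 45773 and 1740 to 41332 for RANKL+I-BET against RANKL, 13090 to 61708 and 1402 to 60297 for RANKL+I-BET against untreated, and 52275 to 72747 and 31927 to 72487 for I-BET against untreated. Without untreated replicate 1, 3 lists passed for RANKL against untreated and 1 for RANKL+I-BET against untreated, adjusted over 26 list tests, all with a smaller share than the comparator; with the replicate block as well, which has fewer comparator regions, 0 passed in either, at ratios of similar size for the 3 lists (-1.17, -2.06 and -1.38). The log2 odds ratio of RANKL-only regions in both RANKL+I-BET libraries was 0.15 to 2.51 over the alternatives that keep both libraries, the lowest being the block without untreated replicate 1. In RANKL+I-BET replicate 2 alone, without untreated replicate 1, it was -0.27 against mixed regions and 0.67 against crossed ones. In RANKL+I-BET replicate 1 alone it was then 0.70 and 0.096.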

Other observations

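Except for the shift test on the replicate 1 lists and the share of weak peaks, the tests in this part were chosen after the results had been seen. Over all 7 libraries, 1823 regions were called in all 4 libraries with RANKL and in none of the 3 without it, and 84 in the reverse. Magi1 and Scg5, which encodes a neuroendocrine chaperone, had 5 of the 1823 each, and Bcar3, Nrg1, Rapgef5, Slc7a14 and the chemokine gene Xcl1 had 4 each (chosen after their values were seen). Among list members Jun had 3 and Atp6v1c1 2, and single regions lay at Jdp2, Fosl2 and Spry2, at the NF-kB genes Nfkbiz and Rel, at the chemokine gene Ccl3, at Ptgs2, at the interferon response genes Ddx58 and Ifi44, at the macrophage regulators Maf, Irf8, Cebpb, Bcl6 and Runx1, at the receptor genes Tlr2, Tlr4, Marco and Adgre1, at Odc1 and at the collagen gene Col3a1. The macrophage identity and osteoclast lists alone had 852 and 701 of the 344401 merged regions. List members were not tested against other genes here, so these counts show no excess at them.

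The libraries split by replicate number more than by treatment. Of the 35 splits of the 7 libraries into 4 and 3, the split by number had the highest log2 ratio, 2.98 (2.74 to 3.09), with 2746 regions in all 4 libraries numbered 2 only and 703 in all 3 numbered 1 only. Randomly placed background calls could not account for all of the 703. Over 100 random shifts of the lists of RANKL and RANKL+I-BET replicate 1 the number was 244 to 366. The shifts do not test background calls that recur at the same positions, so these stay open. Of the 703 regions 3.7% lay within 1 kb of a gene end, against 8.12% of the 2746 and 4.23% of all regions with the ends moved by 1 Mb. The split of the 4 libraries with the highest background pileup had a ratio of 0.48, and with lists of equal length the ratio of the split by number was 2.93, which argues against depth and list length as the whole cause. A difference of culture, day or batch between the numbers stays open, since the labels record none, and no biological explanation was tested.

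The split by RANKL had a log2 ratio of 1.15 (0.91 to 1.34), and 5 of the 35 splits reached it, the highest other being 2.98 for the split by number, so chance cannot be excluded over all splits. Among the 18 splits that put the same replicate numbers on each side it was the highest (1 of 18, highest other 0.541), and 18 splits are too few for a share under 0.05. With a -log10 q of at least 5 it was the second of these 18.

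RANKL-only regions were more often called with RANKL and I-BET together than untreated-only regions. Background calls of untreated replicate 1 may account for part of this, since the log2 odds ratio against mixed regions went from 1.07 to 0.656 without that library. The lower bound stayed at 0.569, above 0, but the interval covers no variation between libraries. In RANKL+I-BET replicate 2 alone that ratio was -0.27 against all mixed regions and 0.67 against crossed ones, so its sign depended on the comparator. In RANKL+I-BET replicate 1 alone, where the depth of replicate 2 plays no part, the ratio was 1.34 against untreated-only regions (lower bound 1.17). With untreated replicate 1 left out as well, it was 0.70 (0.62 to 0.78) against all mixed regions and 0.096 (0.017 to 0.17) against crossed ones. Setting both sources aside thus left little of the ratio against crossed regions. An effect of RANKL that I-BET leaves in place at these regions stays open as a hypothesis, and the blocked ratio without untreated replicate 1 was 0.15 (0.05 to 0.25).

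Untreated replicate 1 had 52975 regions that no other library called. Of these 0.825% had a peak with a -log10 q of at least 5, against 43.6% of the regions it shared. Calls near the threshold of the peak caller would give this. The share was not taken for regions that other libraries called alone, which may also be weak, so it does not set this library apart. Greater depth is unlikely as the source, since 3 libraries (RANKL replicate 1 and both RANKL+I-BET libraries) had a higher background pileup and fewer regions of their own. No biological explanation was tested for this library.

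The highest peak of 4 libraries (untreated, RANKL and RANKL+I-BET replicate 1, and I-BET replicate 2) lay on chromosome 2 from about 22587086 to 22590732, with deposited folds of 2221 to 3047. In untreated, RANKL and RANKL+I-BET replicate 2 it lay on chromosome 4 from about 80002138 to 80005384, with folds of 1343 to 3217. Regions on chromosome X made up 0.702% of the regions of untreated replicate 1 and 1.24% to 1.57% in the other 6 libraries.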
